A study of Mus musculus with 18 samples.

How the data were processed

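RNA from mouse embryoid bodies was measured on 18 single-channel Affymetrix expression arrays. The labels call the 3 arrays of each of the 6 groups biological replicates, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the stem cells had grown on mitotically inactive mouse fibroblasts, 100 ng of total RNA per sample with an RNA integrity number above 9 was labelled with biotin by a 3' in vitro transcription kit, and induction was on day 2 with 1 µg/ml doxycycline. The deposited values were signal intensity on a linear scale, with 1 value for each of 45101 probe sets on each array. GCOS was the software used, per the submitters' processing notes; the signal algorithm and its scaling target are not given in the sources used here. In the deposited intensity values the 2% trimmed mean was 150 on every array, so the authors' values had been scaled per array. No other table or column of per-sample values was used.

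The values were transformed to log2(signal + 32). Array medians on that scale lay within 0.092 of each other, under the limit of 0.25 set for adding a normalization, and none was added. After 64 control probe sets were left out, 34958 probe sets were matched to 1 gene (34754 of them by Entrez identifier), 932 to several genes and 9160 to none. A probe set was kept if its group mean in at least 1 group reached the 40th percentile of all values, a signal of 13.3. Of the probe sets with 1 gene 25881 were kept, and the one with the highest mean over all arrays stood for its gene, which gave 14273 genes, 6674 of them with several kept probe sets. Probe sets without a single gene name were tested separately. Probe sets whose identifier marks possible matches to other transcripts are named as such in the text.

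Differential expression was tested with limma 3.58.1 in R 4.3.3: 1 mean per group, 12 residual degrees of freedom, contrasts for each comparison, moderated variances with an intensity trend, and 2-sided p-values adjusted by the Benjamini-Hochberg method over genes. A gene was called at an adjusted p under 0.05. The contrasts were induced minus uninduced at each time and averaged over times, later minus earlier time in uninduced arrays, and the differences between times of the induction effect. The named genes followed a fixed rule. For induced against uninduced they were Msgn1 and the 12 largest rises and 12 largest falls among called genes whose 3 induced arrays all lay beyond all 3 uninduced arrays. For the uninduced course from 12 h to 48 h they were the 10 largest in each direction by the same rule, and for each difference of effects the 5 largest called in each direction. For each list up to 4 called members with the largest changes were named, or, with none called, up to 2 with values only. Clone names and predicted genes were passed over in naming.

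Of the 559 genes in 28 lists of pathways, developmental stages and cell types, 31 had no probe set matched to 1 gene. Brachyury (T) was not tested in any list. Limma's camera compared each list with the other genes at a preset inter-gene correlation of 0.01, and p-values were adjusted over a contrast's lists. Camera with an estimated correlation and fry were run beside it. The p-values of fry test whether a list's genes move on balance in 1 direction, and its mixed p-values whether they change in either direction; neither compares a list with other genes. Counts of list members were also adjusted over the list alone. Correlations of effects across genes were computed for 6 pairs of contrasts that share no array. Array quality was described by medians, replicate correlations and the 3' to 5' ratios of Actb and Gapdh control probe sets, compared between groups by a 2-sided exact permutation test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

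The comparisons, tests, filter, lists, naming rule and other settings to try were fixed before the data were examined. The other settings were quantile normalization, no filter and a filter at the 60th percentile, another offset in the logarithm, the mean of a gene's probe sets, analysis at probe set level, moderated variances without a trend or with a robust trend, the arrays of a comparison alone, a block for the replicate number, and leaving out each array in turn. Whether replicate numbers pair the arrays was checked by correlating, within each time, the deviations from the group mean of arrays with the same number. At 24 h these correlations were 0.2, 0.14 and 0.44, at 12 h 0.01, 0.072 and -0.067, and at 48 h -0.13, -0.066 and 0.083. The highest correlations with another number at 24 h were 0.2, 0.11 and -0.26, so only the arrays numbered 3 stood clearly apart in this way. Since every correlation of the same number at 24 h was over 0.1, the numbers were treated as pairing arrays there, and a block was tried as an added alternative.

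The steps were tested on simulated data of 14273 genes with each gene's overall mean and residual spread. Of the genes changed in induced 12 h arrays 82% were recovered at 1.5-fold and 100% at 2-fold and 4-fold, and 7 of 198 calls were false. In data without correlation between genes, camera called a list raised 1.5-fold and 0 other lists of 28. Correlated lists were not tested. The p-values measure the spread between the replicates of these cultures.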

Results

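Gene expression was measured on 18 arrays in embryoid bodies, the floating aggregates in which embryonic stem cells begin to differentiate. The mouse line carries a Flag-tagged Msgn1 that doxycycline switches on from a cassette. Msgn1 is a basic helix-loop-helix transcription factor of the presomitic mesoderm, the tissue that gives rise to the somites. Doxycycline (1 µg/ml) was added on day 2 of differentiation, and induced and uninduced embryoid bodies were collected 12, 24 and 48 h later, with 3 arrays in each of the 6 groups. No group received doxycycline without the cassette. The deposited signal was on a linear scale and ran from 0.0187 to 16870 over 45101 probe sets. Array medians lay between 18.8 and 22.2. Replicates correlated at 0.990 to 0.994 on the log2 scale, and no 2 arrays held identical values. After dim probe sets were removed, 14273 genes were tested. Changes are differences of group means of log2(signal + 32), given with the standard error of the fit, and folds refer to that same quantity. In the lists, a pair of numbers adjusted over the list alone counts members higher and lower, and the adjusted p of camera with an estimated correlation is given where a list's call was lost with it. Signals are means with the SD of the 3 arrays in a group. The number of arrays limits the precision of every value.

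Msgn1 itself was higher in all 9 induced arrays than in any uninduced array. Its signal was 70.6 ± 6.07 in induced and 19.0 ± 5.45 in uninduced embryoid bodies at 12 h, 59.0 ± 7.47 against 11.2 ± 5.60 at 24 h, and 51.4 ± 6.18 against 6.14 ± 2.21 at 48 h. The log2 change was 1.01 ± 0.116, 1.08 ± 0.116 and 1.13 ± 0.116 at the 3 times (limma adjusted p = 1.15e-05, 2.59e-06 and 3.43e-07). At 48 h the probe set stood between the 62.1 and 65.2 percentiles of the induced arrays and between the 18.6 and 30.3 percentiles of the uninduced ones. The uninduced signals all lay under the offset of 32, and their group means at 24 h and 48 h under the 13.3 of the filter, so no change of Msgn1 between uninduced times is given. The sources used here do not say whether this probe set matches the transgene, the endogenous gene or both, so the values measure the label and not the dose of the induced protein.

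**Figure D1:**
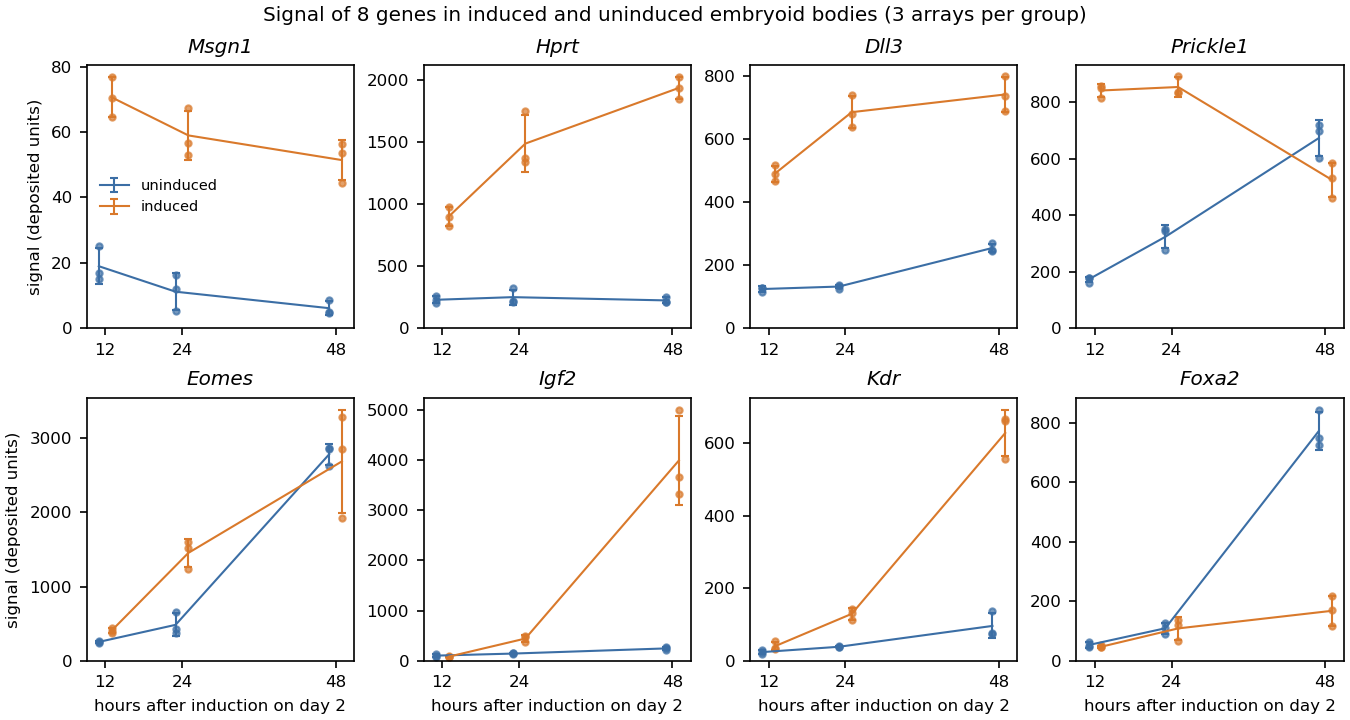
Signal in deposited units (vertical axis, from 0) against hours after induction (horizontal axis) for 8 genes, with a point per array, lines through group means and bars of 1 SD, in induced and uninduced embryoid bodies (n = 3 arrays per group). Igf2 reached 3988 ± 882 in induced arrays at 48 h against 247 ± 26.5 in uninduced ones.

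At 12 h, which asks for the earliest response to Msgn1, the genes with the largest rises included ligands and regulators of signalling in segmenting mesoderm. Prickle1, a planar cell polarity gene, rose from a signal of 173 ± 9.50 to 841 ± 23.0, a 4.27-fold rise. The Notch ligand Dll3 rose from 124 ± 8.10 to 489.6 ± 25.6, and the Notch ligand Dll1 from 87.2 ± 8.17 to 318 ± 23.5. Wnt5a, which encodes a Wnt ligand, rose 3.21-fold, and the ephrin receptor gene Epha4 rose 2.71-fold. Further large rises were those of Rasgrp3, an exchange factor for Ras proteins (1.92 ± 0.147), Hprt, a purine salvage enzyme (1.84 ± 0.123), and the transcriptional cofactor Cited1 (1.66 ± 0.166). Fabp7, which encodes a fatty acid binding protein, rose by 1.37 ± 0.139, the laminin gene Lama1 by 1.37 ± 0.110, the neurogenic transcription factor gene Neurod1 by 1.24 ± 0.129 and Prcd by 1.24 ± 0.113. The highest adjusted p among these 12 genes was 4.18e-06. Falls were smaller: the largest was that of Kbtbd11, which fell by 0.88 from a signal of 365 ± 47.6 to 183 ± 8.12. Psmb8, a subunit of the immunoproteasome, the autophagy receptor gene Calcoco2, the fatty acid transporter gene Slc27a2, Slc35d3, Ddah1, Tafa5, Nphs1, Hopx, Apba2, Zfp428 and Sertad4 also fell, with log2 changes from -0.65 for Psmb8 to -0.50 for Sertad4 and adjusted p up to 0.0494. Probe sets of a symbol differed for Prickle1 (1 of 3 called), Epha4 (3 of 5), Kbtbd11, Psmb8, Tafa5 and Hopx (1 of 2 each) and Ddah1 (1 of 4), and the probe set of Apba2 passed at gene level but not among all probe sets. Of the 12 falls, only Kbtbd11 and Ddah1 kept the call whichever single array was left out; the others reached adjusted p between 0.0725 for Hopx without induced 12 h replicate 2 and 0.194 for Apba2.

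The list for presomitic and segmenting mesoderm was higher at 12 h: of 27 measured members 6 rose and 21 did not pass (9 and 1 adjusted over the list alone). Dll3, Cited1, Dll1 and Epha4 had the largest rises in it, and the list's median change was 0.18 (adjusted p = 2.41e-11). In the Notch pathway, of 32 measured members 5 rose and 27 did not pass (6 and 0 adjusted over the list alone), and the list was higher (adjusted p = 1.16e-05). Beside the ligands, the receptor gene Notch1 rose by 0.77 ± 0.140 and Hes6, a basic helix-loop-helix factor, by 0.96 ± 0.0873. Mesenchymal transition genes were higher as a list (adjusted p = 1.16e-05, and adjusted p = 0.119 with an estimated correlation), while of 22 measured members 1 rose and 21 did not pass (5 and 0 adjusted over the list alone); Cdh11, a mesenchymal cadherin gene, rose by 0.68 ± 0.129. The feeder fibroblast list, which shares 3 members with the mesenchymal one, was higher too (adjusted p = 0.0213, and adjusted p = 0.329 with an estimated correlation). Of 24 measured members 1 rose and 23 did not pass (3 and 0 adjusted over the list alone), with Fstl1, a secreted follistatin-like protein gene, at 0.90 ± 0.0676. Naive pluripotency genes were lower as a list (adjusted p = 7.33e-04, and adjusted p = 0.234 with an estimated correlation). Of 19 measured members 1 fell and 18 did not pass (0 and 4 adjusted over the list alone), the fall being that of the nuclear receptor gene Nr5a2 (-0.50 ± 0.121). Primed epiblast genes were lower as a list (adjusted p = 7.33e-04, and adjusted p = 0.241 with an estimated correlation), though of 15 measured members 15 did not pass (1 and 5 adjusted over the list alone) and 6 had an unadjusted limma p under 0.05; Lef1, a Wnt effector gene, stood at 0.51 ± 0.125 and Fst, a follistatin gene, at -0.50 ± 0.158.

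The S phase list (adjusted p = 0.0452, and adjusted p = 0.329 with an estimated correlation) and the glycolysis and hypoxia list (adjusted p = 0.00210, and adjusted p = 0.466 with an estimated correlation) were also higher at 12 h, and the interferon response list was lower (adjusted p = 7.33e-04, and adjusted p = 0.180 with an estimated correlation). No other list passed. For Wnt targets and feedback genes, of 20 measured members 1 rose and 19 did not pass (3 and 0 adjusted over the list alone), the rise being that of Dact1, a Wnt modulator gene (1.16 ± 0.0967). Among FGF pathway genes, of 23 measured members 3 rose and 20 did not pass (4 and 1 adjusted over the list alone). The feedback inhibitor genes Spry4 (0.60 ± 0.110), Dusp6 (0.49 ± 0.107) and Spry2 (0.40 ± 0.0786) rose. In the Tgfb, Nodal and Bmp pathway, of 24 measured members 2 rose and 22 did not pass (4 and 2 adjusted over the list alone); the Bmp target genes Id1 and Id4 rose by 0.74 ± 0.0988 and 0.67 ± 0.127. Among epithelial adhesion genes, of 27 measured members 3 rose and 24 did not pass (3 and 1 adjusted over the list alone), with the keratin gene Krt8 at 0.60 ± 0.0958, the claudin gene Cldn4 at 0.46 ± 0.107 and the plakophilin gene Pkp2 at 0.42 ± 0.0873. Single members rose in the endothelial and blood list (Etv2, 0.52 ± 0.116), the definitive endoderm list (Cldn4), the extraembryonic endoderm list (Lama1) and the anterior Hox list (Hoxb3, 0.58 ± 0.125); 1, 3, 2 and 1 members of these were higher when adjusted over the list alone. No member passed limma's test in the primitive streak, cardiac and lateral mesoderm, neural, somite and dermomyotome, trophoblast, core pluripotency or posterior Hox lists, where 5, 3, 5, 0, 3, 3 and 2 genes had an unadjusted p under 0.05. Adjusted over the list alone, 3 were higher and 2 lower in the primitive streak list, 2 higher in the neural list, 2 higher in the trophoblast list, 1 higher in the posterior Hox list and none in the rest. In them Eomes, a T-box gene of the streak, stood at 0.61 ± 0.164, Lhx1 at 0.51 ± 0.165, Nes at 0.72 ± 0.181, Irx3 at 0.32 ± 0.102, Hand1 at 0.40 ± 0.157, Bmp4 at -0.35 ± 0.232, Twist1 at 0.15 ± 0.117, Tcf15 at -0.13 ± 0.0848, Tdgf1 at 0.34 ± 0.104, Lefty2 at 0.26 ± 0.101, Hoxd13 at 0.52 ± 0.138 and Hoxa9 at -0.28 ± 0.120. The median, the mean and the camera direction were not all of 1 sign for the core pluripotency, Wnt, FGF, epithelial adhesion and posterior Hox lists. The probe sets of Hes6 and Pkp2 are of a type that can also match other transcripts. Calls of Nr5a2, Spry4, Dusp6, Spry2, Cldn4, Pkp2, Cdh11, Etv2, Hoxb3 and Id4 ended without 1 array, at adjusted p from 0.0579 for Id4 (without uninduced 12 h replicate 1) to 0.207 for Nr5a2. Nr5a2 and Cldn4 passed at gene level, but none of their probe sets passed among all probe sets.

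Across all genes at 12 h, 154 passed limma's test, 128 higher and 26 lower, and 20 of the higher ones changed at least 2-fold. At an unadjusted p under 0.05 there were 1606 genes, where chance alone gives 713.7. Of the 28 lists, 9 passed camera with the preset correlation, 6 up and 3 down, and 2 passed with an estimated correlation. The count of genes fell to 94 without uninduced 12 h replicate 1, 93 without replicate 2, 97 without induced 12 h replicate 1, 74 without replicate 2 and 100 without replicate 3.

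At 24 h more genes were called than at 12 h. Aplnr, the apelin receptor gene of early mesoderm, rose from a signal of 77.5 ± 24.2 to 670 ± 197, a 6.33-fold rise. The receptor gene Pdgfra rose from 38.0 ± 7.87 to 209.6 ± 35.3, and Cyp26a1, whose product breaks down retinoic acid, from 96.0 ± 20.2 to 388 ± 72.2. Dll3 (4.36-fold), Hprt (5.42-fold), Rasgrp3 (4.27-fold), Fabp7 (4.13-fold), Wnt5a (4.08-fold) and Cited1 (3.22-fold) rose as at 12 h. Greb1l rose by 2.14 ± 0.161, Cdh11 by 1.66 ± 0.129 and Gfra2, a receptor gene for neurturin, by 1.60 ± 0.126. The highest adjusted p of these 12 genes was 7.91e-07. Kbtbd11 (-0.95) and Slc35d3 (-0.90) fell most, and Nr0b1, a nuclear receptor gene of naive stem cells, fell by 0.85, from 702 ± 40.4 to 378 ± 67.8. Lgals3, a galectin gene, Serpinf2, Spink10, the adaptor gene Irs4, Slc27a2, Lypd6b, the hyaluronan synthase gene Has1, the water channel gene Aqp3 and Nphs1 fell as well, with log2 changes from -0.85 for Lgals3 to -0.64 for Nphs1 and adjusted p up to 0.0362. Probe sets of a symbol differed for Greb1l, Kbtbd11 and Irs4 (1 of 2 called each), Pdgfra (2 of 3), Gfra2 (1 of 4) and Aqp3 (1 of 3), and the probe set of Has1 did not pass among all probe sets. The probe set of Gfra2 is of a type that can also match other transcripts. Serpinf2, Lypd6b, Has1 and Aqp3 lost the call without 1 array, at adjusted p = 0.0557, 0.0618, 0.180 and 0.0635 at most, Aqp3 only without induced 24 h replicate 3.

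Lists of the segmenting mesoderm, the primitive streak and several pathways were higher at 24 h. In the presomitic and segmenting mesoderm list, of 27 measured members 16 rose and 11 did not pass (18 and 1 adjusted over the list alone), with Dll3, Cyp26a1, Cited1 and Dact1 (1.44 ± 0.0967) changing most (adjusted p = 3.28e-21). In the primitive streak list, of 19 measured members 8 rose and 11 did not pass (11 and 2 adjusted over the list alone). Eomes rose from a signal of 485 ± 153 to 1453 ± 187, Lhx1 by 1.46 ± 0.165, the homeobox gene Mixl1 by 1.19 ± 0.188 and Sp5 by 0.88 ± 0.160 (adjusted p = 9.78e-09). Wnt targets and feedback genes were higher, and of 20 measured members 8 rose and 12 did not pass (13 and 1 adjusted over the list alone), with Lef1 at 0.84 ± 0.125 and Sp8 at 0.70 ± 0.135 (adjusted p = 3.27e-10). In the Notch pathway, of 32 measured members 9 rose and 23 did not pass (12 and 0 adjusted over the list alone). The feedback gene Nrarp rose by 1.12 ± 0.105, Notch1 by 1.01 ± 0.140 and Dll1 by 0.86 ± 0.128 (adjusted p = 6.70e-06). Mesenchymal transition genes were higher as a list (adjusted p = 7.44e-11). Of 22 measured members 10 rose and 12 did not pass (13 and 2 adjusted over the list alone), among them Pdgfra, Cdh11, the chemokine receptor gene Cxcr4 (1.20 ± 0.125) and the fibronectin gene Fn1 (0.73 ± 0.150). In the endothelial and blood list, of 24 measured members 7 rose and 17 did not pass (8 and 0 adjusted over the list alone), with Fli1 at 1.27 ± 0.138, Kdr at 1.19 ± 0.146, Etv2 at 0.85 ± 0.116 and Tal1 at 0.80 ± 0.116 (adjusted p = 2.15e-06). Extraembryonic endoderm genes were higher as a list (adjusted p = 7.69e-06). Of 20 measured members 7 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone), and the members that rose most were Pdgfra and the basement membrane genes Lama1 (1.45 ± 0.110), Col4a1 (0.83 ± 0.110) and Col4a2 (0.78 ± 0.130). Anterior Hox genes were higher, and of 7 measured members 3 rose and 4 did not pass (4 and 0 adjusted over the list alone): Hoxb3 at 0.88 ± 0.125, Hoxb2 at 0.88 ± 0.170 and Hoxb1 at 0.75 ± 0.122 (adjusted p = 9.67e-05). In the cardiac and lateral mesoderm list, of 26 measured members 5 rose and 21 did not pass (7 and 0 adjusted over the list alone), among them Actc1 (0.91 ± 0.113), Gata6 (0.66 ± 0.130), Gata4 (0.65 ± 0.122) and Msx1 (0.64 ± 0.101); it was higher (adjusted p = 8.28e-05, and adjusted p = 0.0883 with an estimated correlation).

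Pluripotency and epithelial lists were lower at 24 h with the preset correlation. Among the naive pluripotency genes, of 19 measured members 1 rose, 5 fell and 13 did not pass (3 and 9 adjusted over the list alone). Nr0b1, Nr5a2 (-0.51 ± 0.121) and Dppa3 (-0.45 ± 0.126) fell, and the T-box gene Tbx3 rose (0.51 ± 0.142) (adjusted p = 9.26e-05, and adjusted p = 0.0642 with an estimated correlation). In the primed epiblast list, of 15 measured members 1 rose, 3 fell and 11 did not pass (1 and 9 adjusted over the list alone); the transcription factor genes Pou3f1 (-0.58 ± 0.0817) and Sall2 (-0.43 ± 0.101) and the transporter gene Slc7a3 (-0.48 ± 0.126) fell, and Lef1 rose (adjusted p = 1.97e-04, and adjusted p = 0.0883 with an estimated correlation). Epithelial adhesion genes were lower as a list (adjusted p = 0.00743, and adjusted p = 0.203 with an estimated correlation). Of 27 measured members 2 rose, 2 fell and 23 did not pass (3 and 6 adjusted over the list alone). Grhl2 (-0.44 ± 0.114) and Epcam (-0.23 ± 0.0635) fell, while Dsp (0.65 ± 0.133) and Krt8 (0.42 ± 0.0958) rose. Core pluripotency genes did not pass as a list. Of 14 measured members 2 rose, 2 fell and 10 did not pass (2 and 4 adjusted over the list alone), namely Lefty2 (0.59 ± 0.101) and Tdgf1 (0.45 ± 0.104) upward and Dppa2 (-0.57 ± 0.154) and Dppa4 (-0.35 ± 0.0844) downward. The germ cell (adjusted p = 2.77e-04), p53 target (adjusted p = 0.00134, and adjusted p = 0.0587 with an estimated correlation) and interferon response (adjusted p = 0.00134, and adjusted p = 0.0866 with an estimated correlation) lists were lower too, and the glycolysis and hypoxia (adjusted p = 0.00491, and adjusted p = 0.447 with an estimated correlation) and the G2 and M phase (adjusted p = 0.0311, and adjusted p = 0.0587 with an estimated correlation) lists were higher. The remaining lists did not pass. In the Tgfb, Nodal and Bmp pathway, of 24 measured members 4 rose and 20 did not pass (8 and 4 adjusted over the list alone), with Id1 at 0.79 ± 0.0988 and Smad6, an inhibitor gene of Bmp signalling, at 0.76 ± 0.123. In the FGF pathway, of 23 measured members 3 rose, 1 fell and 19 did not pass (3 and 1 adjusted over the list alone). Fgf10 (0.89 ± 0.131), Fgfr1 (0.50 ± 0.136) and Spred1 (0.47 ± 0.0799) rose and Fgf4 (-0.44 ± 0.0944) fell. For definitive endoderm, of 17 measured members 3 rose and 14 did not pass (4 and 1 adjusted over the list alone). Lhx1, Cxcr4 and Hhex (0.58 ± 0.122) rose, and the list's median was of the opposite sign to its mean. In the somite and dermomyotome list, of 12 measured members 2 rose, 1 fell and 9 did not pass (3 and 1 adjusted over the list alone). Twist1 (0.62 ± 0.117) and Foxc1 (0.59 ± 0.117) rose and Tcf15 (-0.33 ± 0.0848) fell. In the neural list, of 16 measured members 1 rose, 1 fell and 14 did not pass (3 and 2 adjusted over the list alone), Irx3 at 0.50 ± 0.102 and Sox3 at -0.41 ± 0.114, and the mean was of the opposite sign to the median and the test. For feeder fibroblasts, of 24 measured members 3 rose, 1 fell and 20 did not pass (5 and 1 adjusted over the list alone). Fstl1 (1.07 ± 0.0676), the smooth muscle gene Tagln (0.70 ± 0.119) and the collagen gene Col1a2 (0.57 ± 0.127) rose, and the chemokine gene Ccl2 fell (-0.50 ± 0.139). In the trophoblast list Eomes alone of 13 measured members passed, also when adjusted over the list alone. No posterior Hox gene of 11 passed limma's test, 3 had an unadjusted p under 0.05, and 1 was higher and 1 lower when adjusted over the list alone, with Hoxa7 at -0.61 ± 0.190 and Hoxd13 at 0.47 ± 0.138. With arrays of the same number at 24 h sharing a block, a setting added after the data were seen, Hoxa7 passed (adjusted p = 0.0433). Dppa2, Fgfr1, Dsp and Msx1 were measured by probe sets of a type that can also match other transcripts. Nr5a2, Tbx3, Dppa3, Dppa2, Tdgf1, Dppa4, Slc7a3, Sall2, Tcf15, Fgfr1, Fgf4, Dsp, Grhl2, Krt8, Epcam, Sox3, Hhex, Col1a2 and Ccl2 lost the call without 1 array, at adjusted p from 0.0520 for Dsp (without uninduced 24 h replicate 1) to 0.270 for Ccl2. Tbx3, Dppa3, Dppa2, Slc7a3, Tcf15, Fgfr1, Grhl2, Epcam, Sox3 and Ccl2 passed at gene level, but none of their probe sets passed among all probe sets.

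Over all genes, 558 passed at 24 h, 416 higher and 142 lower; 37 of the higher ones and none of the lower ones changed at least 2-fold, with 2175 genes at an unadjusted limma p under 0.05. Of the 28 lists, 17 passed camera, 11 up and 6 down, and 9 passed with an estimated correlation. Both 24 h arrays numbered 3 stood apart from the other 24 h arrays in the Actb 3' to 5' ratio, at 1.95 uninduced and 2.10 induced against 1.53 to 1.68, and without them 325 genes passed. The count was 333 without uninduced 24 h replicate 1 and 306 without induced 24 h replicate 2; with arrays of the same number at 24 h sharing a block it was 725.

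At 48 h the genes with the largest rises included some of lateral mesoderm and blood vessels, and those with the largest falls included some of endoderm and epiblast. The growth factor gene Igf2 rose 14.2-fold, from 247 ± 26.5 to 3988 ± 882, and Pmp22, a membrane protein gene, 9.16-fold, from 86.3 ± 39.6 to 1033 ± 239. The transcription factor genes Foxf1 and Hand2, of lateral mesoderm, rose from 9.89 ± 1.27 to 268 ± 118 and from 16.6 ± 7.21 to 265 ± 65.6. Bmp4, a ligand that patterns ventral mesoderm, rose by 2.45 ± 0.232, Kdr, a receptor gene for vascular endothelial growth factor, by 2.39 ± 0.146, Tbx3 by 2.18 ± 0.142 and Msx2 by 2.02 ± 0.145. Hprt (2.94 ± 0.123), Asb4 (2.30 ± 0.129), Gfra2 (2.27 ± 0.126) and the proprotein convertase gene Pcsk5 (2.15 ± 0.154) completed the 12 largest rises, and the highest adjusted p among them was 1.16e-07. Foxa2, a forkhead gene of endoderm and node, was lower by 2.04, at 168 ± 50.7 in induced against 772 ± 63.3 in uninduced arrays. Falls were also found for Irs4 (-1.81), Slc27a2 (-1.70), Cer1, an antagonist gene of Nodal and Bmp (-1.64), and Trh, a hormone precursor gene (-1.63). The stem cell gene Eras, Enpp3, the pluripotency gene Foxd3, Calcr, Myrf, Fgf5, a marker of primed epiblast, and Myb fell with log2 changes from -1.50 for Eras to -1.31 for Myb. Probe sets of a symbol differed for Foxf1, Hand2 and Irs4 (1 of 2 called each), Gfra2 and Enpp3 (3 of 4 each) and Tbx3 (2 of 3). Those of Gfra2, Pcsk5, Eras and Myb are of a type that can also match other transcripts. No call of these 24 genes ended when 1 array was left out.

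Several mesodermal lists were higher at 48 h. In the cardiac and lateral mesoderm list, of 26 measured members 20 rose and 6 did not pass (22 and 0 adjusted over the list alone), at a median change of 0.85 (adjusted p = 5.52e-23). In the endothelial and blood list, of 24 measured members 15 rose and 9 did not pass (16 and 1 adjusted over the list alone). Beside Kdr, the transcription factor genes Fli1 (1.69 ± 0.138), Tal1 (1.53 ± 0.116) and Sox7 (1.42 ± 0.120) rose most (adjusted p = 1.05e-13). Mesenchymal transition genes were higher, and of 22 measured members 18 rose and 4 did not pass (19 and 0 adjusted over the list alone), among them the repressor gene Zeb1 (1.65 ± 0.157), Cxcr4 (1.44 ± 0.125), Fn1 (1.32 ± 0.150) and Pdgfra (1.30 ± 0.141) (adjusted p = 7.03e-21). In the presomitic and segmenting mesoderm list, of 27 measured members 19 rose, 1 fell and 7 did not pass (21 and 1 adjusted over the list alone). Cited1 (1.44 ± 0.166), Dll3 (1.43 ± 0.0807) and Evx1 (1.23 ± 0.153) rose and Cer1 fell (adjusted p = 1.51e-14). Anterior Hox genes were higher, and of 7 measured members 5 rose and 2 did not pass (6 and 0 adjusted over the list alone), with Hoxb2 at 1.95 ± 0.170, Hoxb3 at 1.59 ± 0.125, Hoxb1 at 1.52 ± 0.122 and Hoxd1 at 0.71 ± 0.120 (adjusted p = 4.02e-09). In the Tgfb, Nodal and Bmp pathway, of 24 measured members 12 rose, 4 fell and 8 did not pass (13 and 5 adjusted over the list alone), led by Bmp4, Msx2, Smad6 (1.80 ± 0.123) and Id1 (1.65 ± 0.0988) (adjusted p = 4.24e-06). Wnt targets and feedback genes were higher as a list (adjusted p = 1.54e-05). Of 20 measured members 8 rose, 1 fell and 11 did not pass (11 and 1 adjusted over the list alone), with Apcdd1 at 1.76 ± 0.234, Nkd1 at 1.15 ± 0.138 and Lef1 at 0.73 ± 0.125. In the Notch pathway, of 32 measured members 10 rose, 2 fell and 20 did not pass (12 and 3 adjusted over the list alone). Notch1 (1.04 ± 0.140) and Hey2 (1.02 ± 0.120) rose and Dtx1 fell (-0.73 ± 0.0936) (adjusted p = 0.00586, and adjusted p = 0.0719 with an estimated correlation). Extraembryonic endoderm genes were higher as a list (adjusted p = 3.18e-04, and adjusted p = 0.0719 with an estimated correlation). Of 20 measured members 8 rose, 2 fell and 10 did not pass (9 and 3 adjusted over the list alone), and those that rose most, Sox7, Pdgfra, Col4a1 (1.08 ± 0.110) and Col4a2 (1.04 ± 0.130), are also made by mesodermal and vascular cells. The feeder fibroblast list was higher (adjusted p = 0.00661, and adjusted p = 0.149 with an estimated correlation). Of 24 measured members 9 rose, 1 fell and 14 did not pass (9 and 3 adjusted over the list alone), the matrix genes Fbln2 (1.23 ± 0.151) and Col5a2 (0.98 ± 0.102) and Fstl1 (0.95 ± 0.0676) rising and the chemokine gene Cxcl12 falling (-1.08 ± 0.115).

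Epiblast and epithelial lists were lower at 48 h. In the primed epiblast list, of 15 measured members 1 rose, 12 fell and 2 did not pass (1 and 14 adjusted over the list alone), among them Enpp3, Fgf5, Pou3f1 (-1.28 ± 0.0817) and Slc7a3 (-1.14 ± 0.126) (adjusted p = 2.34e-16). Core pluripotency genes were lower (adjusted p = 1.05e-08). Of 14 measured members 1 rose, 7 fell and 6 did not pass (1 and 10 adjusted over the list alone), with Foxd3, Utf1 (-1.18 ± 0.127), Sox2 (-1.06 ± 0.0750) and the Nodal antagonist gene Lefty1 (-1.03 ± 0.135) falling most. In the epithelial adhesion list, of 27 measured members 2 rose, 16 fell and 9 did not pass (3 and 20 adjusted over the list alone). Rab25 (-1.27 ± 0.148), the claudin gene Cldn6 (-0.999 ± 0.129), Epcam (-0.93 ± 0.0635) and Crb3 (-0.84 ± 0.122) fell (adjusted p = 1.27e-14). Definitive endoderm genes were lower, and of 17 measured members 2 rose, 7 fell and 8 did not pass (2 and 8 adjusted over the list alone), Foxa2, Cer1 and Trh falling and Cxcr4 rising most (adjusted p = 2.67e-04). The naive pluripotency list did not pass. Of 19 measured members 2 rose, 7 fell and 10 did not pass (2 and 8 adjusted over the list alone), with Tbx3 and Klf4 (0.76 ± 0.168) upward and Nr0b1 (-0.85 ± 0.130) and Fbxo15 (-0.52 ± 0.140) downward. In the primitive streak list, of 19 measured members 5 rose, 2 fell and 12 did not pass (5 and 3 adjusted over the list alone). Evx1, Mesp1 (1.11 ± 0.165), Cdx2 (0.81 ± 0.149) and Wnt3 (0.68 ± 0.133) rose, and the median was of the opposite sign to the mean and the test. In the FGF pathway, of 23 measured members 5 rose, 5 fell and 13 did not pass (6 and 7 adjusted over the list alone). Fgf10 (1.32 ± 0.131), Fgf3 (1.14 ± 0.153) and Fgfr3 (0.59 ± 0.177) rose and Fgf5 fell, and the mean was of the opposite sign to the median and the test. Somite and dermomyotome genes did not pass as a list. Of 12 measured members 4 rose and 8 did not pass (4 and 0 adjusted over the list alone), Twist1 at 0.72 ± 0.117, the retinoic acid synthesis gene Aldh1a2 at 0.67 ± 0.189, Foxc1 at 0.52 ± 0.117 and Pax3 at 0.45 ± 0.142. In the neural list, of 16 measured members 2 rose, 2 fell and 12 did not pass (2 and 4 adjusted over the list alone). Sox3 (-1.30 ± 0.114) and Sox2 fell, Ncam1 (0.99 ± 0.122) and Irx3 (0.39 ± 0.102) rose. In the trophoblast list, of 13 measured members 4 rose and 9 did not pass (5 and 1 adjusted over the list alone). Hand1 (1.08 ± 0.157), Gata3 (1.05 ± 0.173), Cdx2 and Ets2 (0.56 ± 0.145) rose, and the median and mean differed in sign. No posterior Hox gene of 11 passed limma's test, in all or when adjusted over the list alone, 1 had an unadjusted p under 0.05, and Hoxb6 stood at 0.31 ± 0.122 and Hoxa9 at -0.24 ± 0.120. Apcdd1, Crb3 and Wnt3 were measured by probe sets of a type that can also match other transcripts. Fbxo15, Aldh1a2, Pax3, Fgfr3, Irx3 and Ets2 lost the call without 1 of the 48 h arrays, at adjusted p from 0.0926 for Irx3 to 0.208 for Fgfr3. The probe sets of Pax3 did not pass among all probe sets.

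In total 1773 genes passed at 48 h, 979 higher and 794 lower, of which 129 and 43 changed at least 2-fold; 3427 had an unadjusted limma p under 0.05. Camera called 16 of the 28 lists, 12 up and 4 down, and 12 passed with an estimated correlation. The Gapdh 3' to 5' ratio, a sign of RNA quality, was 0.906 ± 0.00769 in induced and 0.874 ± 0.00461 in uninduced arrays at 48 h (SD, n = 3; 2-sided exact permutation p = 0.1, the smallest this design allows).

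**Figure D2:**
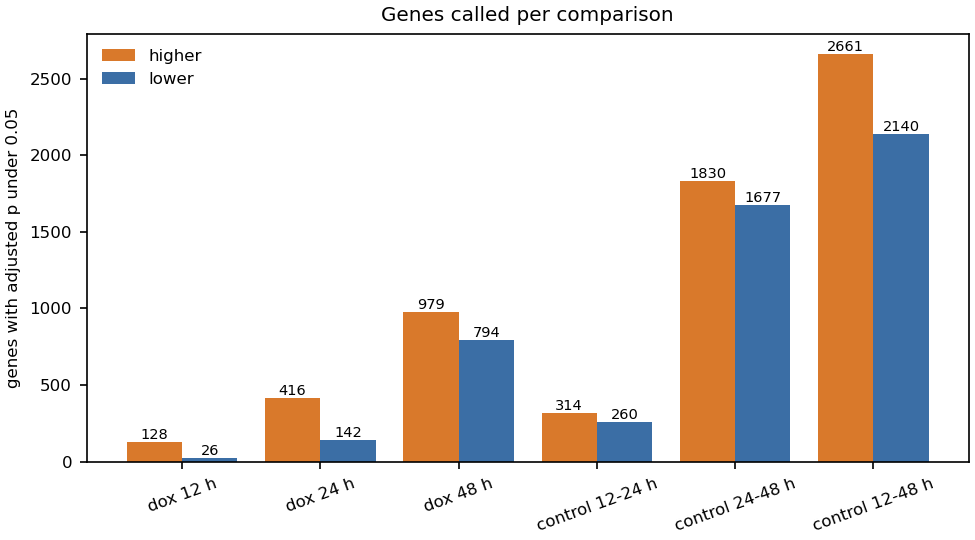
Number of genes with an adjusted p under 0.05 (vertical axis, from 0), higher and lower, for induced against uninduced embryoid bodies at 3 times and for 3 intervals of the uninduced time course (horizontal axis, dox for the former and control for the latter). Induced arrays had 128, 416 and 979 higher genes at 12, 24 and 48 h.

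Averaged over the 3 times, where a large effect at 1 time can suffice, 1865 genes passed, 1138 higher and 727 lower. Called higher at all 3 times were 46 genes. Of them the rules above had named Hprt, Rasgrp3, Fabp7, Greb1l, Msgn1, Dll1, Dll3, Notch1, Cited1, Epha4, Wnt5a, Cdh11, Etv2, Lama1, Fstl1, Hoxb3 and Id1. Called lower at each time were the 5 genes Ajuba, Gadd45a, Glrx, Slc27a2 and Slc35d3, named after their values were seen. Higher at 12 h without being called higher at 48 h were 78 genes, and 740 were called higher at 48 h and in neither direction at the earlier times. Of the 28 lists 19 passed for the average, and 14 with an estimated correlation.

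**Figure D3:**
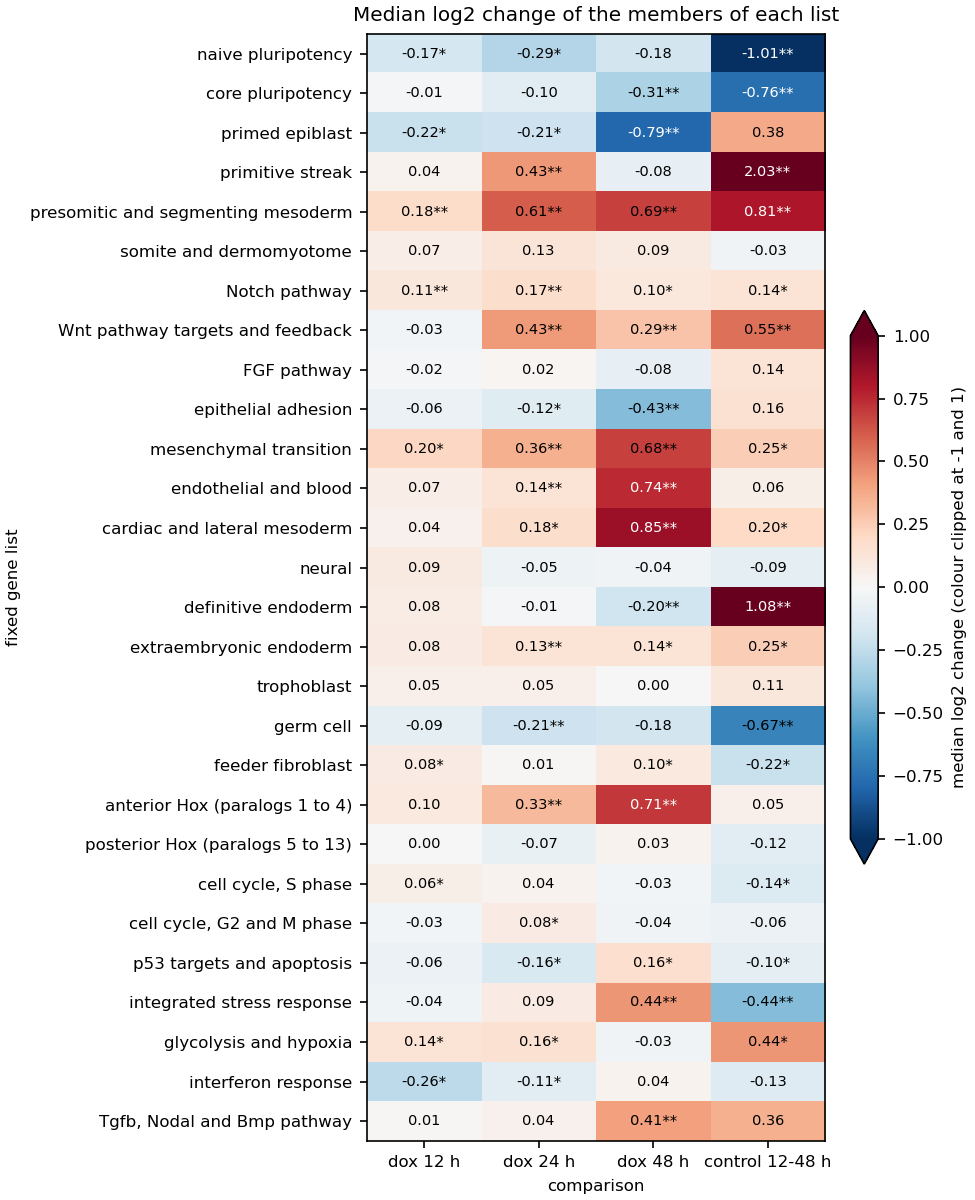
Median log2 change of the measured members of each of the 28 fixed lists (vertical axis) for induced against uninduced embryoid bodies at 3 times and for the uninduced course from 12 h to 48 h (horizontal axis), with colour clipped at the ends of its scale. A first star marks a camera call with the preset correlation and a second one a call that held with an estimated correlation; cardiac and lateral mesoderm at 48 h had a median of 0.85.

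The uninduced time course asks how embryoid bodies change without induced Msgn1. From 12 h to 48 h genes of the primitive streak, mesoderm and endoderm rose, and naive and core pluripotency genes fell. Aplnr rose 17.7-fold, from 65.9 ± 22.9 to 1690 ± 328, Mixl1 13.5-fold, from 77.4 ± 19.9 to 1450 ± 266, and Eomes 9.81-fold, from 254 ± 13.4 to 2780 ± 139.6. Cyp26a1 (3.63 ± 0.157), the mesoderm gene Mesp1 (3.58 ± 0.165), Lhx1 (3.47 ± 0.165), the Wnt antagonist gene Frzb (3.36 ± 0.143), Foxa2 (3.24 ± 0.175), Sp5 (3.14 ± 0.160) and the endoderm gene Sox17 (3.06 ± 0.149) rose as well. Dppa2, a pluripotency gene, fell by 3.12, from 2255 ± 219 to 235 ± 55.4. Falls were also called for Fam25c (-2.69), Nr0b1 (-2.68), Morc1 (-2.65), Epas1 (-2.60), Fgf4 (-2.54), Mageb16 (-2.45), Rhox5 (-2.41), Dppa4 (-2.35) and Ooep (-2.26). The highest adjusted p of these 20 genes was 5.12e-12, and none of their calls ended when 1 array was left out. The probe sets of Sox17 and Dppa2 are of a type that can also match other transcripts.

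In the primitive streak list, of 19 measured members 16 rose and 3 did not pass (17 and 0 adjusted over the list alone), at a median change of 2.03 (adjusted p = 6.63e-18). The presomitic and segmenting mesoderm list was higher (adjusted p = 1.16e-09). Of 27 measured members 17 rose, 2 fell and 8 did not pass (17 and 2 adjusted over the list alone), with Cyp26a1, Mesp1, the Wnt inhibitor gene Dkk1 (2.74 ± 0.133) and Cer1 (2.32 ± 0.223) rising most. Definitive endoderm genes were higher, and of 17 measured members 11 rose, 2 fell and 4 did not pass (11 and 2 adjusted over the list alone), Gsc at 2.53 ± 0.171 (adjusted p = 2.05e-07). In the Wnt list, of 20 measured members 12 rose, 1 fell and 7 did not pass (13 and 1 adjusted over the list alone), with Tnfrsf19 at 1.96 ± 0.119 beside Frzb, Sp5 and Dkk1 (adjusted p = 2.05e-07). Mesenchymal transition genes were higher as a list (adjusted p = 0.00270, and adjusted p = 0.187 with an estimated correlation). Of 22 measured members 10 rose, 2 fell and 10 did not pass (10 and 3 adjusted over the list alone), with Cdh11 at 1.99 ± 0.129, the cadherin gene Cdh2 at 1.87 ± 0.113, Cxcr4 at 1.85 ± 0.125 and Pdgfra at 1.71 ± 0.141. Extraembryonic endoderm genes, where of 20 measured members 9 rose, 2 fell and 9 did not pass (10 and 2 adjusted over the list alone), were higher (adjusted p = 0.0228, and adjusted p = 0.276 with an estimated correlation), with Gata6 at 2.17 ± 0.130. In the cardiac and lateral mesoderm list, of 26 measured members 10 rose, 2 fell and 14 did not pass (11 and 2 adjusted over the list alone), Bmp2 at 1.87 ± 0.154, Msx1 at 1.35 ± 0.101 and Msx2 at 0.94 ± 0.145 (adjusted p = 0.0417, and adjusted p = 0.350 with an estimated correlation). In the Notch pathway, of 32 measured members 13 rose, 4 fell and 15 did not pass (13 and 4 adjusted over the list alone), with Nrarp at 1.26 ± 0.105, Dll3 at 0.87 ± 0.0807, Dner at 0.82 ± 0.129 and Hes1 at 0.81 ± 0.130 (adjusted p = 0.0439, and adjusted p = 0.219 with an estimated correlation). Naive pluripotency genes were lower, and of 19 measured members 1 rose, 17 fell and 1 did not pass (1 and 18 adjusted over the list alone), Zfp42 at -2.11 ± 0.0974 and Fbxo15 at -1.56 ± 0.140 (adjusted p = 3.02e-14). In the core pluripotency list, of 14 measured members 2 rose, 10 fell and 2 did not pass (2 and 10 adjusted over the list alone), Gdf3 at -1.89 ± 0.102 and Lefty1 at -1.69 ± 0.135 (adjusted p = 6.66e-07). The feeder fibroblast list was lower over the course (adjusted p = 0.00296, and adjusted p = 0.187 with an estimated correlation). Of 24 measured members 3 rose, 8 fell and 13 did not pass (3 and 9 adjusted over the list alone), with S100a4 at -1.10 ± 0.139, Ccl2 at -0.99 ± 0.139, Postn at -0.88 ± 0.149 and Acta2 at -0.82 ± 0.101.

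Several lists changed in both directions over the course and did not pass. In the primed epiblast list, of 15 measured members 8 rose, 5 fell and 2 did not pass (8 and 5 adjusted over the list alone). Fst (2.82 ± 0.158) and Wnt8a (1.52 ± 0.133) rose, Pou3f1 (-1.47 ± 0.0817) and Enpp3 (-1.14 ± 0.122) fell. In the FGF pathway, of 23 measured members 9 rose, 4 fell and 10 did not pass (9 and 6 adjusted over the list alone), with Fgf8 at 2.70 ± 0.156, Flrt3 at 1.34 ± 0.135 and Fgf5 at 1.07 ± 0.136. In the Tgfb, Nodal and Bmp pathway, of 24 measured members 13 rose, 8 fell and 3 did not pass (13 and 8 adjusted over the list alone), Cfc1 at 1.52 ± 0.168. In the epithelial adhesion list, of 27 measured members 9 rose, 4 fell and 14 did not pass (10 and 5 adjusted over the list alone). Krt19 (1.76 ± 0.173), Krt8 (1.39 ± 0.0958) and Dsp (1.10 ± 0.133) rose and Grhl2 (-1.11 ± 0.114) fell. In the endothelial and blood list, of 24 measured members 4 rose, 4 fell and 16 did not pass (4 and 4 adjusted over the list alone). Kdr (1.16 ± 0.146) and Cdh5 (0.48 ± 0.128) rose, Pecam1 (-0.69 ± 0.210) and Tek (-0.56 ± 0.125) fell. In the neural list, of 16 measured members 3 rose, 5 fell and 8 did not pass (3 and 5 adjusted over the list alone). Nes (1.63 ± 0.181) and Irx3 (0.86 ± 0.102) rose, Sox2 (-0.96 ± 0.0750) and Tubb3 (-0.91 ± 0.107) fell. In the somite and dermomyotome list, of 12 measured members 2 rose, 1 fell and 9 did not pass (2 and 1 adjusted over the list alone), Tcf15 at -1.15 ± 0.0848, Foxc1 at 0.86 ± 0.117 and Twist1 at 0.55 ± 0.117. In the trophoblast list, of 13 measured members 2 rose, 2 fell and 9 did not pass (1 and 2 adjusted over the list alone), Rhox6 at -0.65 ± 0.159, Rhox9 at -0.46 ± 0.122 and Hand1 at 0.41 ± 0.157. Hoxb1 (0.43 ± 0.122) alone rose of 7 anterior Hox genes, also adjusted over the list alone, and Hoxd13 (-0.43 ± 0.138) alone fell of 11 posterior ones, where none passed adjusted over the list alone. No probe set of Hand1 passed among all probe sets. Pecam1, Hand1 and Hoxd13 lost the call without 1 array, at adjusted p = 0.122 (without uninduced 48 h replicate 1), 0.198 and 0.134. Acta2, Msx1 and Dsp were measured by probe sets of a type that can also match other transcripts.

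Over the whole course 4801 genes passed limma's test, 2661 higher and 2140 lower, and 242 and 210 of these changed at least 2-fold. From 24 h to 48 h 3507 genes passed, 1830 higher and 1677 lower. From 12 h to 24 h 574 passed, 314 higher and 260 lower. This last count was 289 without uninduced 12 h replicate 1, 189 without replicate 2, 237 without uninduced 24 h replicate 1, 242 without replicate 2 and 906 without replicate 3, and 1249 without both 24 h arrays numbered 3. Camera called 16 of the 28 lists from 12 h to 48 h, 9 up and 7 down, and 8 held with an estimated correlation.

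A test of the difference between times asks which genes responded to induction differently as the culture aged. The effect on Igf2 grew by 1.65 ± 0.20 from 12 h to 24 h and by 2.40 ± 0.20 from 24 h to 48 h, and that on Aplnr grew by 2.36 ± 0.273 and then fell by 1.73. Prickle1, raised by 2.09 at 12 h, stood at 1.32 at 24 h and -0.34 at 48 h, and its effect fell by 2.43 from 12 h to 48 h. The effect on Eomes fell by 1.64 from 24 h to 48 h, from 1.55 to -0.08, while its uninduced signal rose. Foxa2 had an effect of -0.04 at 24 h, which did not pass, and the difference to 48 h was -2.001 ± 0.247. Effects on Pmp22 (2.86 ± 0.251), Foxf1 (2.86 ± 0.301), Hand2 (2.37 ± 0.221) and Bmp4 (2.21 ± 0.328) grew from 24 h to 48 h, and that on Cer1 fell by 1.59. From 12 h to 24 h the effects on Gfra2 (1.33 ± 0.178), Greb1l (1.28 ± 0.227) and Pdgfra (1.26 ± 0.199) grew, and those on Serpinf2 (-1.41 ± 0.249), Neurod1 (-1.05 ± 0.183) and Prickle1 (-0.77 ± 0.131) fell. From 12 h to 48 h the effects on Igf2 (4.06 ± 0.20), Pmp22 (3.35 ± 0.251), Bmp4 (2.80 ± 0.328), Hand2 (2.68 ± 0.221) and Foxf1 (2.50 ± 0.301) grew, and those on Foxa2 (-1.94 ± 0.247), Cer1 (-1.80 ± 0.316), Trh (-1.76 ± 0.155) and Myb (-1.55 ± 0.171) fell. Calls of Greb1l, Serpinf2 and Neurod1 for 12 h to 24 h ended without 1 array, at adjusted p up to 0.0656, 0.0632 and 0.0644.

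The effect changed in 15 genes from 12 h to 24 h (12 up, 3 down), in 444 from 24 h to 48 h (209 up, 235 down) and in 781 from 12 h to 48 h (405 up, 376 down). The first of these counts was 23 without uninduced 24 h replicate 3, 26 without induced 24 h replicate 1, 9 without induced 24 h replicate 2, and 28 with arrays of the same number at 24 h sharing a block. Between 24 h and 48 h the effect on cardiac and lateral mesoderm genes grew (adjusted p = 5.34e-18), with 11 of 26 members passing upward. For endothelial and blood genes it grew as well (adjusted p = 6.30e-08), while it fell for primed epiblast genes (adjusted p = 2.85e-13), epithelial adhesion genes (adjusted p = 1.06e-11) and definitive endoderm genes (adjusted p = 6.30e-08). The effect on primitive streak genes grew from 12 h to 24 h (adjusted p = 9.36e-08, and adjusted p = 0.0926 with an estimated correlation) and fell from 24 h to 48 h (adjusted p = 4.05e-04, and adjusted p = 0.159 with an estimated correlation). Of the 28 lists, 12, 15 and 17 passed for the 3 differences, and 0, 12 and 11 passed with an estimated correlation. Fry called 3 lists for 12 h to 24 h.

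Across genes, the induction effects at 12 h and 24 h correlated at r = 0.407 (Spearman rho = 0.279), those at 24 h and 48 h at 0.444 (0.319), and those at 12 h and 48 h at 0.190 (0.119). They depended on the offset: with log2(value + 1) these 3 values of r were 0.209, 0.290 and 0.123. Genes are not independent replicates, so these 6 correlations, 3 here and 3 with the control course, are descriptions. Called higher at both 12 h and 24 h were 79 genes, where 3.73 would be shared by chance, and 232 were called higher at both 24 h and 48 h, where chance gives 28.5. The effect at 24 h correlated with the uninduced change from 12 h to 48 h at r = 0.475 (rho = 0.408), and no array enters both. Of the 416 genes higher at 24 h, 304 also rose over the uninduced course (77.6 by chance), and of the 142 lower ones 99 also fell (21.3 by chance). The effect at 12 h correlated with the uninduced change from 24 h to 48 h at r = 0.208 (rho = 0.185), with 51 genes higher in both (16.4 by chance). With log2(value + 1) the values of r with the control course were 0.340 for the effect at 24 h and 0.114 for that at 12 h. The effect at 48 h and the uninduced change from 12 h to 24 h correlated at r = 0.00978 (rho = 0.0315); 72 genes were lower with induction and rose over the course (17.5 by chance), and 48 were higher in both (21.5 by chance).

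**Figure D4:**
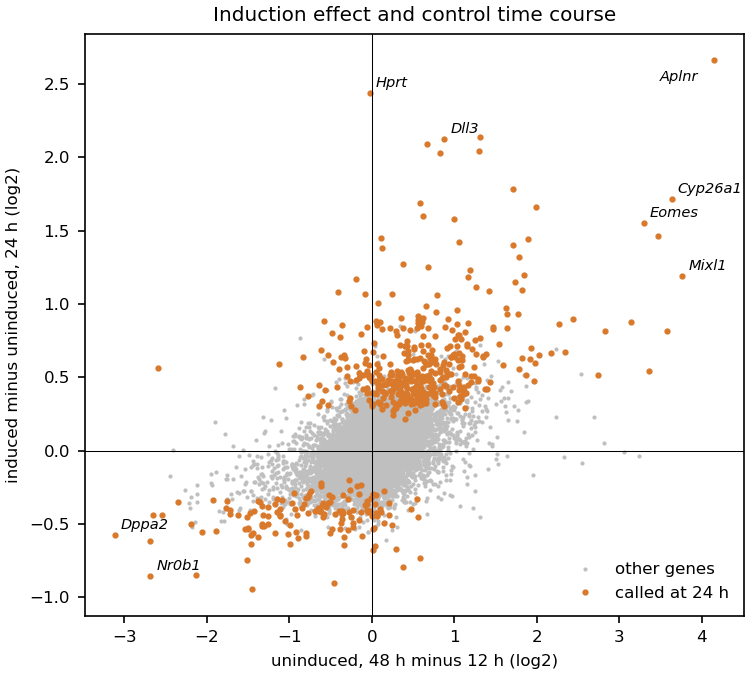
Log2 change of induced against uninduced embryoid bodies at 24 h (vertical axis) against the uninduced change from 12 h to 48 h (horizontal axis), with a point per gene and the 558 genes called at 24 h in colour. Aplnr lies at 2.66 and 4.15, and r over all genes was 0.475.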

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

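The comparison of splits by the times whose grouping they kept was chosen only after the split counts were seen; the other tests in this part were planned. From 12 h to 24 h (15 genes changed) the induction effect grew for Aplnr (2.36), Igf2 (1.65), Gfra2 (1.33), Greb1l (1.28) and Pdgfra (1.26). It fell for Serpinf2 (-1.41), Neurod1 (-1.05) and Prickle1 (-0.77). From 24 h to 48 h (444 genes) it grew for Pmp22 (2.86), Foxf1 (2.86), Igf2 (2.40), Hand2 (2.37) and Bmp4 (2.21). It fell for Foxa2 (-2.001), Aplnr (-1.73), Prickle1 (-1.66), Eomes (-1.64) and Cer1 (-1.59). From 12 h to 48 h (781 genes) it grew for Igf2 (4.06), Pmp22 (3.35), Bmp4 (2.80), Hand2 (2.68) and Foxf1 (2.50). It fell for Prickle1 (-2.43), Foxa2 (-1.94), Cer1 (-1.80), Trh (-1.76) and Myb (-1.55). Probe sets differed as given above.

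Probe sets that match no gene or several genes carried a signal outside the gene table: of 4616 tested, 7 passed limma's test for induced against uninduced at 12 h, 26 at 24 h and 170 at 48 h. The strongest of them had a log2 change of 0.689 at 12 h, 0.748 at 24 h and 1.93 at 48 h, the last from a mean signal of 51.8 to 293.

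For each comparison of 3 arrays with 3, the 10 splits of the 6 arrays cannot give a share under 0.05, the smallest being 0.1. At 12 h the real split called 154 genes and 9 lists, and the highest of the others called 1 gene and 3 lists. The real split at 24 h called 558 genes and 17 lists against 0 genes and 13 lists, and that at 48 h 1773 genes and 16 lists against 0 genes and 14 lists. Over the uninduced course the real splits called 574 genes from 12 h to 24 h, 3507 from 24 h to 48 h and 4801 from 12 h to 48 h, the last with 16 lists, where the highest others called 0, 2 and 0 genes and 11 lists. At 24 h, where the numbers were treated as pairing the arrays, the other splits that part all 3 pairs also called 0 genes with limma.

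For the average over times, 1 of 100 drawn splits within times, the real one, called as many genes (1865, highest other 341), so chance is unlikely. The change of the effect from 12 h to 48 h called 781 genes, and 3 of 100 splits called as many, the highest other 1340. For 12 h to 24 h (15 genes) 12 of 100 splits called as many, the highest other 159, and for 24 h to 48 h (444 genes) 8 of 100, the highest other 1443. For these 3 changes of the effect the test cannot decide on chance, since a split that mixes 1 time alone keeps the other time's effect. Splits with several times the real count point to a structure of the samples. Of the splits as large for 12 h to 24 h, 24 h to 48 h and 12 h to 48 h, 11, 7 and 2 kept the real grouping of at least 1 time, as it was or with the groups swapped. They so carried that time's whole induction effect. Splits that kept the grouping of no time called at most 7, 3 and 1 genes.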

How the results depend on the processing

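The block within 24 h and the removal of both 24 h arrays numbered 3 were chosen after the data were seen; the other alternatives were planned. Of 358 called values of named genes, 74 lost the call when 1 array was left out, and 6 lost it under quantile normalization, 24 without the filter, 28 with the mean of a gene's probe sets, 18 without the variance trend, 1 with the robust trend, 22 with log2(value + 1), 4 with log2(value + 100) and 6 with the block over all times. Without both 24 h arrays numbered 3, 23 of the 103 called values of the contrasts with 24 h lost the call and 2 gained it; the block within 24 h ended none and added 4. One value reversed: Tnfrsf10b at 48 h, 0.54 with all arrays, was -0.0632 without uninduced 48 h replicate 3, because another probe set of the gene was then the brightest; it was 0.0504 to 0.279 without 4 other arrays for the same reason. Of the 74 lost calls this choice lay behind 2 (Tnfrsf10b, and in part Cenpe); looking for it was decided after the results were seen. With a 2-fold minimum 20, 37 and 172 genes remained at 12, 24 and 48 h, which follows from the added condition. At probe set level 5266 and 7497 probe sets passed for 24 h to 48 h and 12 h to 48 h of the uninduced course, where more features were tested. The 6 arrays of 24 h alone gave 241 genes, with fewer arrays for the spread. Without both 24 h arrays numbered 3, 325 genes passed at 24 h and 1249 for uninduced 12 h to 24 h; the cause was not tested. The change of the effect from 12 h to 24 h gave 9 genes with the mean of probe sets and 28 with the block within 24 h (15 without it); its genes up and down were 8 and 4 without the filter, 9 and 4 without the trend and 10 and 1 with log2(value + 1), against 12 and 3. A replicate block over all times gave 140, 504 and 1717 genes at 12, 24 and 48 h, and the block within 24 h gave 725 at 24 h. Lists called with an estimated correlation were 2 at 12 h, 9 at 24 h and 8 over the uninduced course, and fry called 5 at 12 h. Correlations of effects moved beyond their jackknife error to 0.491 (12 h and 24 h) with the stricter filter, and with log2(value + 1) to 0.209, 0.123, 0.290, 0.114 and 0.340; the cause was not tested. With each array left out in turn, counts ranged from 74 (induced 12 h replicate 2) to 190 genes (uninduced 24 h replicate 3) at 12 h, 306 (induced 24 h replicate 2) to 588 (induced 48 h replicate 1) at 24 h, 1269 (induced 48 h replicate 1) to 1926 (uninduced 24 h replicate 3) at 48 h, 189 (uninduced 12 h replicate 2) to 906 (uninduced 24 h replicate 3) for uninduced 12 h to 24 h, and 9 (induced 24 h replicate 2) to 26 (induced 24 h replicate 1) for the change of the effect from 12 h to 24 h. Low signal limits the smallest changes: genes near the offset of 32 have compressed log2 changes.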

Other observations

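The tests of the integrated stress response list and the bound on single feeder transcripts, the leaving out of the dim ones and the block at 24 h were chosen only after the results were seen; the other tests in this part were planned. Genes of the integrated stress response, a programme of amino acid synthesis and stress signalling, were higher in induced embryoid bodies at 48 h, where of 18 measured members 10 rose and 8 did not pass (12 and 0 adjusted over the list alone). Vldlr rose by 1.43 ± 0.158, the glutathione-degrading enzyme gene Chac1 by 1.06 ± 0.103, the asparagine synthetase gene Asns by 0.81 ± 0.0682 and the serine synthesis gene Psat1 by 0.77 ± 0.0828 (adjusted p = 1.41e-11). At 24 h, of 18 measured members 2 rose and 16 did not pass (3 and 0 adjusted over the list alone), Vldlr at 0.73 ± 0.158 and Asns at 0.31 ± 0.0682. None of 18 members passed limma's test at 12 h, also when adjusted over the list alone, where 5 had an unadjusted p under 0.05 and Vldlr stood at 0.37 ± 0.158 and Trib3 at -0.29 ± 0.113. Over the uninduced course the list was lower. Of 18 measured members 2 rose, 11 fell and 5 did not pass (2 and 11 adjusted over the list alone), with Nupr1 at -1.53 ± 0.149, Trib3 at -0.89 ± 0.113, Vldlr at 1.54 ± 0.158 and Ddit4 at 1.36 ± 0.324 (adjusted p = 1.82e-04). Genes of p53 targets and apoptosis were lower at 24 h (adjusted p = 0.00134, and adjusted p = 0.0587 with an estimated correlation) and higher at 48 h (adjusted p = 0.0212, and adjusted p = 0.119 with an estimated correlation). At 48 h, of 19 measured members 5 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a (0.91 ± 0.0968), Gadd45g (0.68 ± 0.149) and Tnfrsf10b (0.54 ± 0.134) rose and Bcl2l11 (-0.74 ± 0.146) fell. Gadd45a fell at 12 h (-0.43 ± 0.0859), where of 19 measured members 1 fell and 18 did not pass (0 and 1 adjusted over the list alone), and at 24 h (-0.38 ± 0.0859), where of 19 measured members 1 fell and 18 did not pass (0 and 4 adjusted over the list alone). From 12 h to 48 h without induction, of 19 measured members 3 rose, 8 fell and 8 did not pass (4 and 8 adjusted over the list alone), Gadd45a at -1.26 ± 0.0859, Gadd45g at -1.20 ± 0.149, Eda2r at -0.95 ± 0.115 and Sesn2 at -0.71 ± 0.152 (adjusted p = 0.0449, and adjusted p = 0.238 with an estimated correlation). From 24 h to 48 h the effect of induction grew for the stress response list (adjusted p = 8.27e-11) and for the p53 list (adjusted p = 6.35e-06). Tnfrsf10b lost its call at 48 h when any 1 of 5 arrays was left out (adjusted p up to 0.926), each time because another of its probe sets was then the brighter one and stood for the gene. Calls also ended without 1 array for Gadd45a at 12 h (0.0964) and at 24 h without uninduced 24 h replicate 1 (0.0649), and Vldlr and Asns at 24 h (0.0532 and 0.0731). The probe sets of Vldlr, Asns, Psat1, Trib3 and Tnfrsf10b are of a type that can also match other transcripts.

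From 24 h to 48 h the effect of induction on the list of G2 and M phase genes fell (adjusted p = 4.41e-04, and 0.00700 with an estimated correlation), with no single member passing. S phase genes were higher at 12 h as a list (adjusted p = 0.0452, and adjusted p = 0.329 with an estimated correlation), but no member of 23 passed limma's test, also when adjusted over the list alone, with 5 at an unadjusted p under 0.05, Ccne1 at -0.46 ± 0.322 and Ccne2 at 0.25 ± 0.0992. At 24 h none passed either, with 3 at an unadjusted p under 0.05, Tyms at -0.29 ± 0.0984 and Mcm6 at 0.20 ± 0.0565, though Mcm6 passed with arrays of the same number at 24 h sharing a block (adjusted p = 0.0233). At 48 h, of 23 measured members 2 rose, 2 fell and 19 did not pass (2 and 3 adjusted over the list alone). Ccne2 (0.45 ± 0.0992) and Rrm2 (0.23 ± 0.0513) rose, Pola1 (-0.28 ± 0.0867) and Mcm2 (-0.23 ± 0.0665) fell. In uninduced arrays from 12 h to 48 h, of 23 measured members 2 rose, 8 fell and 13 did not pass (2 and 9 adjusted over the list alone), Ccne1 at -1.20 ± 0.322, Ung at -0.50 ± 0.0736, Pola1 at -0.50 ± 0.0867 and Cdt1 at -0.33 ± 0.0566 (adjusted p = 0.0119, and adjusted p = 0.187 with an estimated correlation). Of the G2 and M phase genes, none of 24 passed limma's test at 12 h or 24 h, where 1 and 2 had an unadjusted p under 0.05; Mki67 stood at 0.21 ± 0.147 and Cenpe at 0.19 ± 0.119 at 12 h, and Kif20a at 0.31 ± 0.109 and Ccnb2 at 0.24 ± 0.0743 at 24 h, when the list was higher (adjusted p = 0.0311, and adjusted p = 0.0587 with an estimated correlation). With the block at 24 h Kif20a and Ccnb2 passed (adjusted p = 0.0106 and 0.0404). At 48 h, of 24 measured members 1 fell and 23 did not pass (0 and 0 adjusted over the list alone), Nusap1 at -0.30 ± 0.0950, and over the uninduced course, of 24 measured members 2 rose, 3 fell and 19 did not pass (0 and 2 adjusted over the list alone), Ect2 at -0.61 ± 0.122, Mki67 at 0.41 ± 0.147, Mad2l1 at -0.38 ± 0.0864 and Cenpe at 0.32 ± 0.119. Genes of glycolysis and hypoxia were higher as a list at 12 h (adjusted p = 0.00210, and adjusted p = 0.466 with an estimated correlation) and 24 h (adjusted p = 0.00491, and adjusted p = 0.447 with an estimated correlation); no member passed limma's test at either time, 5 and 4 had an unadjusted p under 0.05, and Adm stood at 0.77 ± 0.316 and 0.85 ± 0.316 and Ndrg1 at 0.51 ± 0.308 and 0.69 ± 0.308. At 48 h, of 22 measured members 1 rose, 2 fell and 19 did not pass (1 and 2 adjusted over the list alone). Vegfa (0.62 ± 0.170) rose, Pdk1 (-0.50 ± 0.0887) and the glucose transporter gene Slc2a1 (-0.33 ± 0.0960) fell, and the mean of the list was of the opposite sign to its median and the test. Over the uninduced course, of 22 measured members 14 rose, 2 fell and 6 did not pass (15 and 2 adjusted over the list alone), Ndrg1 at 2.23 ± 0.308, Aldoc at 1.25 ± 0.236, Pfkl at 1.02 ± 0.157 and Egln3 at 0.84 ± 0.266 (adjusted p = 1.82e-04, and adjusted p = 0.350 with an estimated correlation). Interferon response genes were lower as a list at 12 h (adjusted p = 7.33e-04, and adjusted p = 0.180 with an estimated correlation) and 24 h (adjusted p = 0.00134, and adjusted p = 0.0866 with an estimated correlation): at 12 h, of 17 measured members 1 fell and 16 did not pass (0 and 8 adjusted over the list alone), namely Psmb8, and at 24 h, of 17 measured members 1 fell and 16 did not pass (0 and 2 adjusted over the list alone), Ifi35 at -0.56 ± 0.137. At 48 h, of 17 measured members 3 rose, 1 fell and 13 did not pass (3 and 1 adjusted over the list alone). Usp18 (0.96 ± 0.158), Gbp2 (0.68 ± 0.159) and Tap1 (0.51 ± 0.113) rose and Bst2 fell (-0.87 ± 0.104). Over the uninduced course, of 17 measured members 2 rose, 6 fell and 9 did not pass (2 and 6 adjusted over the list alone), Ifi35 at -1.44 ± 0.137, Ddx58 at -1.05 ± 0.180, Oasl2 at -0.66 ± 0.115 and Usp18 at 0.55 ± 0.158. Germ cell genes were lower at 24 h (adjusted p = 2.77e-04), where of 10 measured members 2 fell and 8 did not pass (0 and 4 adjusted over the list alone), Dppa3 at -0.45 ± 0.126 and Ifitm3 at -0.34 ± 0.0723; at 12 h none of 10 passed limma's test, 1 had an unadjusted p under 0.05, and Sycp3 stood at 0.31 ± 0.111 and Prdm14 at -0.21 ± 0.129. At 48 h, of 10 measured members 1 rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone). Sycp3 (-0.86 ± 0.111), Kit (-0.85 ± 0.149) and Mael (-0.33 ± 0.0975) fell, Ifitm3 rose (0.52 ± 0.0723). Over the uninduced course the list was lower (adjusted p = 1.82e-04). Of 10 measured members 1 rose, 7 fell and 2 did not pass (1 and 7 adjusted over the list alone), Ifitm3 at -1.75 ± 0.0723, Dppa3 at -1.51 ± 0.126, Mael at -1.32 ± 0.0975 and Dazl at -1.15 ± 0.115. Calls ended without 1 array for Psmb8 at 12 h (0.159), Ifi35 (0.112), Ifitm3 (0.0554) and Dppa3 (0.233) at 24 h, Pola1 (0.152), Mcm2 (0.111), Nusap1 (0.150), Vegfa (0.136), Slc2a1 (0.0887), Gbp2 (0.0503, induced 48 h replicate 1) and Mael (0.166) at 48 h, and Ccne1 (0.0604), Mki67 (0.169), Cenpe (0.599), Egln3 (0.166) and Usp18 (0.0647) over the uninduced course, each number being the highest adjusted p; for Cenpe another probe set stood for the gene there. No probe set of Pola1 and Nusap1 at 48 h, or of Cenpe over the uninduced course, passed among all probe sets. Ccne1, Rrm2, Mcm2, Adm, Ndrg1 and Ifi35 were measured by probe sets of a type that can also match other transcripts.

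Hprt was higher in induced arrays at every time, by 1.84 ± 0.123, 2.44 ± 0.123 and 2.94 ± 0.123. Scaling of the arrays is argued against by 11 other housekeeping genes, whose median change at 48 h was 0.0122 (from -0.184 to 0.09). Of 4 flanking genes (median 0.19), Plac1, at a mean signal of 8.78, is too dim to count. Ccdc160 (-0.101) and Phf6 (0.0599) argue against activation of the whole region, but Fam122b rose (0.338). The sources used here do not give the insertion site of the cassette. If it lay beside Hprt, as is known of other A2lox lines, read-through from it may account for the rise, which was not tested directly. Over the uninduced course Hprt changed by -0.0258, as a change that follows doxycycline and not differentiation would. Regulation of Hprt by Msgn1 itself stays open and was not tested.

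The integrated stress response list was higher with induction at 48 h. Doxycycline acting alike at every time is argued against by the list's median effect of -0.0414 at 12 h. The list's median change over the control course was -0.436, so the list fell there. This cannot decide on faster passage along that course, since induced cells ahead at 48 h would match later control times, which were not measured. A late action of doxycycline, or a state of the induced cells, could also stand behind the rise at 48 h. Neither was tested, as no group received doxycycline without the cassette.

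The feeder fibroblast list, of which 4 of 24 members are also in other lists, was higher at 48 h, a call that was lost with an estimated correlation (adjusted p = 0.149), and the stem cells had grown on fibroblasts, with no removal step in the labels. A larger share of fibroblasts in the induced cultures would raise all transcripts abundant in fibroblasts, but the median change of 7 of them was 0.0808 (from -0.397 to 0.843), against 0.747 for the list's called rises. Of the 7, Col1a1 and Lum had uninduced signals at 48 h under the offset of 32 and exclude nothing. The other 5, with signals from 56.4 to 128, had the same median, and for 4 of them, Col3a1, Dcn, Postn and Thy1, the upper 95% bound lay below 0.374. Expression of these matrix genes by differentiating mesoderm may account for the rise and was not tested.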
